A study of Mus musculus with 6 samples.

How the data were processed

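Chromatin accessibility was measured by ATAC-seq, an assay in which the Tn5 transposase cuts open chromatin and attaches sequencing adapters. The 6 samples were mouse neural progenitors made from embryonic stem cells, 3 carrying a control lentivirus (mScarlet) and 3 carrying an Nr6a1 lentivirus (Nr6a1OE). Per the labels' protocols, the culture received 5 µM CHIR99021, a GSK3 inhibitor, on day 2, then 100 nM retinoic acid with 10 nM Smoothened agonist from day 3, and 10 nM Smoothened agonist alone from day 5. Virus was added on day 5, and fluorescent cells were sorted on day 9, with 50000 cells entering each library.

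The authors deposited a single table of raw fragment counts for 52223 consensus intervals in the 6 samples, with a median interval length of 1023 bp (179 to 6178 bp). Per the file headers, the counts were made with featureCounts 2.0.1, counting read pairs, letting a fragment count for every interval it overlapped, and requiring an overlap of at least 0.2 of the fragment. The submitters' processing notes name the mm10 build. The aligner, the peak caller, the treatment of duplicates and mitochondrial reads, any shift of the reads for the Tn5 cut and how the intervals were merged over samples are not given in the sources used here. A fragment that overlapped neighbouring intervals was counted in each, so neighbouring intervals are not fully independent, and intervals in repeated sequence depend on an alignment filter that is not known.

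The depth was 6857763 to 8030029 fragments in intervals per library. On counts simulated from the real means and library sizes over 51526 intervals, the test of Nr6a1OE against mScarlet recovered 30% of 50 planted changes of 0.3 on the log2 scale, 60% of 50 at 0.5, 92% of 50 at 1 and 100% of 50 at 1.5. It called 5 unchanged intervals. A planted list shifted by 0.2 was called and 0 other lists were. The single changes were planted only in intervals above a minimum mean count. Noise was drawn at the common dispersion over all intervals, 0.000217, a measure of spread beyond counting noise. That is below the median trended dispersion of edgeR, 0.000684, and holds no added variation between cultures. The rates therefore do not cover weaker intervals or noisier cultures.

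Intervals were filtered with filterByExpr, which removed 586 and left 51637. Counts were scaled by the trimmed mean of M values (TMM), and the groups were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3), with Benjamini-Hochberg adjusted p under 0.05 and no covariate. An interval with higher accessibility in Nr6a1OE past that threshold is called opened, and one with lower accessibility closed. The standard error (SE) of a log2 fold change was derived from the fold change and its F statistic. CPM values are counts scaled to the library size multiplied by its TMM factor. The labels do not say that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

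Replicates were compared by a chi-square test of counts over intervals with a mean of at least 10 fragments. Every pair within a group differed by more than counting noise (chi-square per degree of freedom 1.04 to 1.10, highest p 7.2e-13), and each library was kept as 1 replicate. So small an excess does not tell separate cultures from technical libraries. Over intervals with a mean of at least 100 fragments, the chi-square per degree of freedom between Nr6a1OE 1 and 3 was 0.997, no more than counting noise. The counts of calls with that pair summed to 1 sample are therefore given among the alternatives. At the same limit mScarlet 2 and 3 gave 1.16, the highest value within a group. Pairs between groups gave 1.21 to 1.54, the lowest for mScarlet 2 with Nr6a1OE 1.

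Gene positions came from a RefSeq table of the GRCm38.p6 assembly, whose coordinates are those of mm10, with the start and end of each gene but no strand and no exons. Each interval was therefore assigned to the protein-coding gene, of 21896, with the nearest end (start or finish of the gene), in place of the transcription start planned, and exons, introns and untranslated regions were not distinguished. Intervals within 1 kb of a gene end, otherwise inside a gene, or intergenic were compared with uncalled intervals by 2-sided Fisher's exact tests, 6 in all, adjusted by Benjamini-Hochberg. Since these classes exclude each other, 2 further Fisher's exact tests, added after the values were seen and not adjusted, compared the inside of genes with intergenic positions among intervals beyond 1 kb. Percentages carry exact (Clopper-Pearson) 95% intervals that cover counting error only.

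The 19 gene lists, with 245 genes, all found in the table, were fixed before the data were examined, as were the test, the rule for named intervals and most alternatives. List members were intervals whose nearest gene end lay within 100 kb. Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, each adjusted over the 19 lists. A 2-sided Fisher's exact test of called intervals per list, adjusted over 38 tests, was added after the calls had been seen. Named intervals were the 10 largest changes in each direction among called intervals whose groups did not overlap and whose higher group averaged at least 50 fragments, up to 3 called intervals of smallest adjusted p per list with at most 1 per gene, and all intervals at Nr6a1. Some results of that rule, and the counts that rest on them, are not reported here.

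The alternatives covered 4 other scalings, DESeq2 1.42.0, limma voom, filters, thresholds, the replicate number as a block, autosomes alone, omission of each library and other assignment distances. Those added later removed chromosome medians, left out chromosomes 6 and 11, summed a pair of libraries, assumed a variation of 10% or 20% between cultures, and assigned intervals to the nearest gene body. No genome sequence was used here, so the search for 17 motifs, the correction for GC content and the check of reads over the coding exons of Nr6a1 were not run. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.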

Results

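Accessible chromatin was compared between neural progenitors carrying a control virus and progenitors carrying an Nr6a1 virus, 4 days after transduction. Nr6a1, also known as germ cell nuclear factor, is an orphan nuclear receptor that represses pluripotency genes as embryonic stem cells differentiate. The question was how its overexpression altered chromatin in these progenitors, whose protocol uses retinoic acid and a Smoothened agonist, signals that give neural cells posterior and ventral character. Fragments in intervals numbered 7347754, 6857763 and 8030029 in mScarlet 1, 2 and 3, and 7035135, 7056536 and 7923767 in Nr6a1OE 1, 2 and 3. The first principal component held 30.4% of the variance and separated the groups, and the second held 18.1%.

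At the Nr6a1 gene itself (mm10, chromosome 2, 38723369 to 38926461), accessibility rose at 1 of 8 intervals. That interval, at 38822994 to 38825616 inside the gene and 100.9 kb from its nearer end, went from 52.4 ± 3.79 CPM in mScarlet to 64.6 ± 2.66 CPM in Nr6a1OE (SD, n = 3 each). Its log2 fold change was 0.30 with an SE of 0.059, and its edgeR quasi-likelihood adjusted p was 1.2e-04. The interval spanning the end of Nr6a1 at 38925508 to 38927373 held 82.5 ± 4.20 CPM in mScarlet and 86.2 ± 2.15 CPM in Nr6a1OE (SD, n = 3 each), a log2 fold change of 0.06 that did not pass (edgeR adjusted p = 0.651). The other 6 Nr6a1 intervals lay between -0.13 and 0.32 on the log2 scale and did not pass. Reads from the viral Nr6a1 copy were not told apart from those of the gene, and the call was lost in DESeq2 (log2 fold change 0.30, adjusted p = 0.0875).

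Across the genome, Nr6a1OE progenitors lost accessibility at 652 intervals and gained it at 242 of 51637 tested. The largest loss among intervals named by rule was inside Pou2f1, which encodes the octamer-binding factor Oct-1. This interval (chromosome 1, 165966173 to 165967254, 36.0 kb from the nearer gene end) fell from 18.8 ± 0.839 to 5.21 ± 0.969 CPM (SD, n = 3 each), a log2 fold change of -1.86 with an SE of 0.14 (edgeR quasi-likelihood adjusted p = 8.58e-35). Intervals inside Col12a1, a collagen gene (chromosome 9, 79605623 to 79606414, -1.76, SE 0.19), and inside Csrnp3 (chromosome 2, 65908347 to 65910261, -1.54, SE 0.22) closed as well. Intergenic intervals that closed lay nearest to Mpped2 (-1.64, 115.0 kb away) and Emcn, which encodes an endothelial sialomucin (-1.54, 151.9 kb). Others lay nearest to the neuregulin receptor gene Erbb4 (-1.51, 236.7 kb) and the cell polarity gene Pard3 (-1.50, 278.6 kb). The interval nearest to the oxygen-sensing prolyl hydroxylase gene Egln3 (-1.49) was 22.6 kb from it. Those nearest to Pabpc4l (-1.71) and Akr1e1 (-1.61) were 423.1 kb and 551.1 kb from the gene. Of these intergenic intervals, all but the one at Egln3 lay beyond the 100 kb limit used for the lists. All 10 of these closed intervals were also called by DESeq2 and in each fit that left out 1 library.

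The largest gain among intervals named by rule lay inside Fam83g (chromosome 11, 61701218 to 61702186), from 3.56 ± 1.08 to 6.89 ± 0.338 CPM (SD, n = 3 each), a log2 fold change of 0.97 with an SE of 0.20 (edgeR adjusted p = 3.5e-04). Intervals 94.1 kb from Supt20 (0.88), inside Arl15 (0.87) and inside Aspscr1 (0.74, chromosome 11) also opened, and these 4 calls held in each fit that left out 1 library. Further gains lay 112.2 kb from Lpp (0.80), 99.3 kb from Stx16 (0.75), and inside Tnrc6b (0.79), Col4a4 (0.78) and the potassium channel gene Kcnq1 (0.74). Another lay 52.3 kb from Gm52481 on chromosome Y (0.83), where reads can be shared with other copies of the sequence. Each of these 6 calls was lost on leaving out a library. Nr6a1OE 2 decided those at Gm52481, Lpp and Col4a4 (edgeR adjusted p = 0.109, 0.216 and 0.0589 without it), and mScarlet 3 the one at Stx16 (0.0918). Tnrc6b was lost without mScarlet 3 or Nr6a1OE 3 (0.0970 and 0.122), and Kcnq1 without mScarlet 1 or Nr6a1OE 3 (0.175 and 0.0914). None of the 10 opened intervals was called by DESeq2.

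The median log2 fold change was -0.68 over closed intervals (quartiles -0.98 and -0.47) and 0.47 over opened ones (quartiles 0.33 and 0.68), against 0.0038 over all tested. A change of at least 1 was seen at 154 closed and 22 opened intervals. In 860 of the 894 called intervals the groups did not overlap, which held for 16.6% of all tested intervals, where chance gives 10%. The counts rest on a small spread between libraries, with a common coefficient of variation of 1.47%, and DESeq2 called 99 closed and 4 opened. With an assumed variation of 10% between cultures 205 closed and 19 opened, and the calls at Nes (edgeR adjusted p = 0.09996), Pax3 (0.587), Gli3 (0.1475), Pax7 (0.778), Sox2 (0.148), Hoxc8 (0.468), Hoxc6 (0.854) and Hoxb9 (0.951), given below, were among those lost. At 20% the calls near Hoxa4, Nfib and Notch1 (edgeR adjusted p = 1, 1 and 0.4295) were lost too, none of the 10 opened intervals above was called, and the 10 closed intervals above stayed. Leaving out mScarlet 1, mScarlet 3, Nr6a1OE 2 or Nr6a1OE 3 lowered the opened count to 98, 158, 146 and 152, and leaving out mScarlet 1, mScarlet 3, Nr6a1OE 1 or Nr6a1OE 3 lowered the closed count to 395, 403, 412 and 421.

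**Figure D1:**
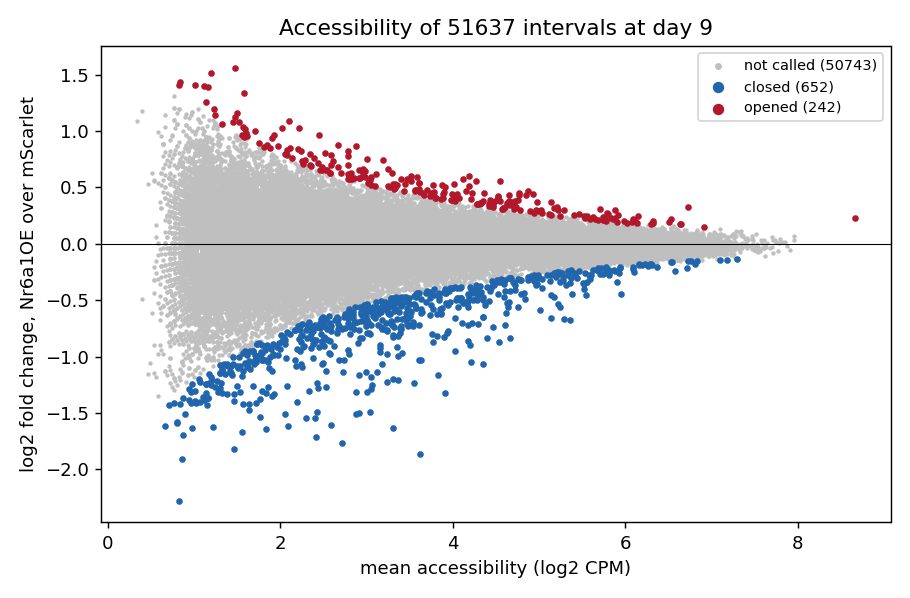
Each point is 1 interval, with mean accessibility in log2 CPM on the horizontal axis and the log2 fold change of Nr6a1OE over mScarlet on the vertical axis, and colours mark intervals called by edgeR at adjusted p under 0.05. The 652 closed intervals reach -2.28 and the 242 opened ones reach 1.56.

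Closed intervals were rarer near gene ends than uncalled ones. Within 1 kb of a gene end were 39 of 652 closed intervals, or 5.98% (95% exact interval 4.29 to 8.09%), and 39 of 242 opened intervals, or 16.1% (11.7 to 21.4%), against 24.7% of uncalled intervals. Fisher's exact test gave an odds ratio of 0.194 for closed (adjusted p = 1.85e-35) and 0.587 for opened intervals (adjusted p = 0.00244). Among intervals beyond 1 kb of any gene end, the inside of genes held 310 of 613 closed (50.6%), 99 of 203 opened (48.8%) and 19951 of 38230 uncalled intervals (52.2%), with no difference by Fisher's exact test for closed (p = 0.439) or opened ones (p = 0.360). More than 100 kb from any gene end lay 32.7% of closed, 14.0% of opened and 14.0% of uncalled intervals. Leaving out mScarlet 1, mScarlet 3 or Nr6a1OE 2 lowered the share of closed intervals near gene ends to 2.78, 3.47 and 3.40%, and in DESeq2 it was 3.03%. The depletion of opened intervals near gene ends did not pass with a limit of 3 kb (28.9%, p = 0.334), with loess offsets (20.5%, p = 0.140) or without Nr6a1OE 2 (20.5%, p = 0.290, all unadjusted, by Fisher's exact test).

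In the list of dorsoventral patterning genes, which divide the neural tube into progenitor domains, 7 of 158 intervals opened and 1 closed. Accessibility rose next to Pax3 and at Pax7, which encode transcription factors of dorsal progenitors, inside Gli3, the main transcriptional repressor of hedgehog signalling, near Irx3, and inside Elp4 near Pax6. The Pax3 interval (chromosome 1, 78196398 to 78198584, 0.4 kb from the gene end) went from 46.4 ± 2.29 to 57.2 ± 1.96 CPM (SD, n = 3 each), a log2 fold change of 0.31 with an SE of 0.062 (edgeR adjusted p = 3.09e-04). The Gli3 interval (chromosome 13, 15485832 to 15487771) had a log2 fold change of 0.57 (SE 0.14, edgeR adjusted p = 0.00393), and the first Pax7 interval (chromosome 4, 139831295 to 139834312) one of 0.26 (SE 0.060, edgeR adjusted p = 0.00261). Named after their values were seen are the second Pax7 interval (0.27), both Irx3 intervals (0.31 and 0.23), the Pax6 interval (1.12, SE 0.30) and the closed interval at Nkx2-2, a gene of ventral progenitors (-0.28). The Pax6 interval did not meet the rule for the largest changes, through few fragments or groups that overlapped. It starts at 105791045 on chromosome 2, and Pax6 ends at 105698410. The Irx3 intervals start at 91793618 (0.31) and 91875475 (0.23) on chromosome 8, and Irx3 spans 91798511 to 91801654.

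The 7 opened dorsoventral intervals compared with 0.740 expected from the share opened overall (Fisher's exact test, adjusted p = 4.04e-04), and 11 opened and 2 closed when adjusted over the list alone. Fisher's exact test takes intervals as independent, which those of 1 gene may not be, and Pax7 and Irx3 each held 2 of the 7. As a set the list did not move to one side (camera adjusted p = 0.363), and its median of about 0 was on the negative side while its mean was 0.017. The calls at Pax3 and Gli3 held in each fit that left out 1 library, and Pax7 at 139831295 was lost without mScarlet 1 or Nr6a1OE 3 (edgeR adjusted p = 0.0711 and 0.0698). The second Pax7 interval, both Irx3 intervals, Pax6 and Nkx2-2 were each lost in 3 to 5 of the 6 such fits (highest edgeR adjusted p = 0.290, 0.238, 0.0989, 0.203 and 0.195). Without mScarlet 1 or Nr6a1OE 2 the list had 2 and 3 opened intervals and its Fisher's exact test did not pass (adjusted p = 0.808 and 0.401). No interval of the list was called by DESeq2.

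Hox genes, which set position along the body axis, were listed by paralogue group. Of 23 intervals at Hox6 to Hox9, 3 opened, at Hoxc8 (0.40, SE 0.11), Hoxc6 (0.25, SE 0.073) and Hoxb9 (0.21, SE 0.063), with edgeR adjusted p of 0.0221, 0.0403 and 0.0437. The list median was 0.13, and 6 intervals opened when adjusted over the list alone. Fisher's exact test, which takes intervals as independent though neighbouring Hox intervals may not be, gave an adjusted p of 0.00319. Camera gave an adjusted p of 1.24e-04, or adjusted p = 0.342 with an estimated correlation. The 56 intervals at Hox1 to Hox5 had a median of 0.05 (camera adjusted p = 0.403). Accessibility fell near Hoxa4 (chromosome 6, 52194451 to 52195128, in the span of Hoxa3), from 29.4 ± 1.66 to 19.2 ± 1.96 CPM (SD, n = 3 each) with a log2 fold change of -0.61 (SE 0.092, edgeR adjusted p = 1.97e-08). None of the 29 intervals at Hox10 to Hox13 was called. The difference between paralogue groups was not itself tested.

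The Hoxa4 call held in each fit that left out 1 library and in DESeq2, which did not call Hoxc8, Hoxc6 or Hoxb9 (adjusted p = 0.692, 0.891 and 1.00). Hoxc8 and Hoxc6 were lost on leaving out any library but Nr6a1OE 1 (highest edgeR adjusted p = 0.168 and 0.295), and Hoxb9 on leaving out any but mScarlet 1 and Nr6a1OE 1 (0.402). Without any library except Nr6a1OE 1, at most 1 Hox6 to Hox9 interval opened and Fisher's exact test did not pass for that list (adjusted p = 0.808 to 1). Hoxb9 lies on chromosome 11 and Hoxa4 on chromosome 6, both of which shifted as a whole, and with chromosome medians removed Hoxb9 (adjusted p = 0.238) and Hoxc6 (0.0528) were no longer called, leaving 1 opened Hox6 to Hox9 interval, at Hoxc8 (Fisher's exact test for the list, adjusted p = 1).

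The 49 intervals at retinoid pathway genes had a median log2 fold change of 0.03 and did not move to one side as a set (camera adjusted p = 0.721).

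At neural progenitor genes, 4 of 99 intervals closed and 0 opened, the same counts as when adjusted over the list alone. The list as a whole did not move down, with a median and a mean of 0.02 each, a camera direction of up that did not pass (adjusted p = 0.518), and 7 intervals higher and 5 lower at an unadjusted p under 0.05. The clearest was inside Nes, the gene of the progenitor intermediate filament nestin (chromosome 3, 87973781 to 87974814), from 53.8 ± 4.44 to 39.2 ± 2.80 CPM (SD, n = 3 each), a log2 fold change of -0.45 with an SE of 0.066 (edgeR adjusted p = 9.35e-09), which held in each fit that left out 1 library and in DESeq2. The others included intervals at Notch1 (-1.38, SE 0.35, a weak interval of 2.73 ± 0.635 CPM in mScarlet, n = 3) and Cdh2 (-0.32, SE 0.091, named after its value was seen). The interval assigned to Sox2 (-0.72, SE 0.19) was intergenic, 78.1 kb from the end of that gene. Fisher's exact test for closed intervals did not pass for this list (adjusted p = 0.470). Notch1 was lost without mScarlet 1, mScarlet 3, Nr6a1OE 2 or Nr6a1OE 3 (highest edgeR adjusted p = 0.122), Sox2 without mScarlet 2, mScarlet 3 or Nr6a1OE 1 (0.174), and Cdh2 without any but Nr6a1OE 2 (0.197). DESeq2 did not call Sox2 (adjusted p = 0.654) or Cdh2 (0.801) and gave no adjusted p for Notch1.

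Early and late temporal genes, which mark successive ages of neural progenitors, each had few called intervals. In the late temporal and gliogenic list, 3 of 97 intervals closed, against 1.22 expected from the share closed overall. They lay 5.0 kb from Nfib (-0.85, SE 0.19, edgeR adjusted p = 0.00156), 70.5 kb from the glutamate transporter gene Slc1a3 (-0.48, SE 0.12, edgeR adjusted p = 0.0132) and 23.6 kb from Sox9 (-0.26, SE 0.072, edgeR adjusted p = 0.0277). Adjusted over the list alone, 1 opened and 5 closed. Camera did not pass for this list (adjusted p = 0.249). In the early list 1 of 60 intervals opened, against 0.281 expected, and 1 when adjusted over the list alone. It lay next to Hmga1, which encodes a chromatin architectural protein (0.15, SE 0.042, edgeR adjusted p = 0.0366). Fisher's exact test did not pass for the closed intervals of the late list or the opened ones of the early list. The early list had a median of 0.07 and a camera adjusted p of 0.0382, or adjusted p = 0.245 with an estimated correlation, and that call was lost without any 1 library except mScarlet 2 (adjusted p = 0.0725 to 0.101). Nfib was lost without Nr6a1OE 2 (edgeR adjusted p = 0.0515), Slc1a3 without mScarlet 1, mScarlet 3, Nr6a1OE 2 or Nr6a1OE 3 (highest 0.136), Sox9 without mScarlet 3 or any Nr6a1OE library (0.364), and Hmga1 without mScarlet 1, mScarlet 2, Nr6a1OE 1 or Nr6a1OE 3 (0.387). DESeq2 called none of these 4 intervals (adjusted p = 0.257, 0.571, 0.804 and 0.835).

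Cell cycle genes had 0 called of 48 intervals but a median of 0.09 (camera adjusted p = 0.0303, or adjusted p = 0.245 with an estimated correlation), a call lost on leaving out any 1 library except mScarlet 2 (adjusted p = 0.0503 to 0.138). Markers of other cell types showed single calls. At post-mitotic neuron genes 1 of 115 intervals closed, inside the neuronal RNA-binding protein gene Elavl4 (-0.37, SE 0.10, edgeR adjusted p = 0.0279). Of 45 neural crest intervals 1 opened, 77.8 kb from Ets1 (0.41, SE 0.12, edgeR adjusted p = 0.0359). Of 28 endothelium and blood intervals 1 closed, inside the VEGF receptor gene Kdr (-0.57, SE 0.16, edgeR adjusted p = 0.0293). Of 27 endoderm intervals 1 closed, in Ttc6 and 75.9 kb from Foxa1 (-0.75, SE 0.21, edgeR adjusted p = 0.0246). Adjusted over the list alone these 4 lists had the same calls, with 1 opened endoderm interval more. Ets1 was lost without any library but mScarlet 2, Kdr and Foxa1 without any but Nr6a1OE 1, and Elavl4 without any but mScarlet 2 and Nr6a1OE 1 (highest edgeR adjusted p = 0.311, 0.276, 0.211 and 0.353). DESeq2 called none of them (adjusted p = 0.841, 0.848, 0.779 and 0.910).

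No interval was called by edgeR at genes of the oligodendrocyte lineage (51 intervals), neurogenesis (55), Hox10 to Hox13 (29), pluripotency and germ line (34), mesoderm (38), the interferon response (12), the p53 response (24) or the cell cycle (48). Over these 8 lists, 27 intervals were higher and 14 lower at an unadjusted p under 0.05, and DESeq2 called 0. Adjusted over the list alone, 2 mesoderm intervals and 1 p53 interval opened. Camera did not pass for any list apart from early temporal, Hox6 to Hox9 and cell cycle (adjusted p = 0.249 to 0.964). Its direction was up while the mean was negative for mesoderm (median 0.03, mean -0.01) and endoderm (0.03, -0.02), and while both were negative for the interferon response (-0.01, -0.02).

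**Figure D2:**
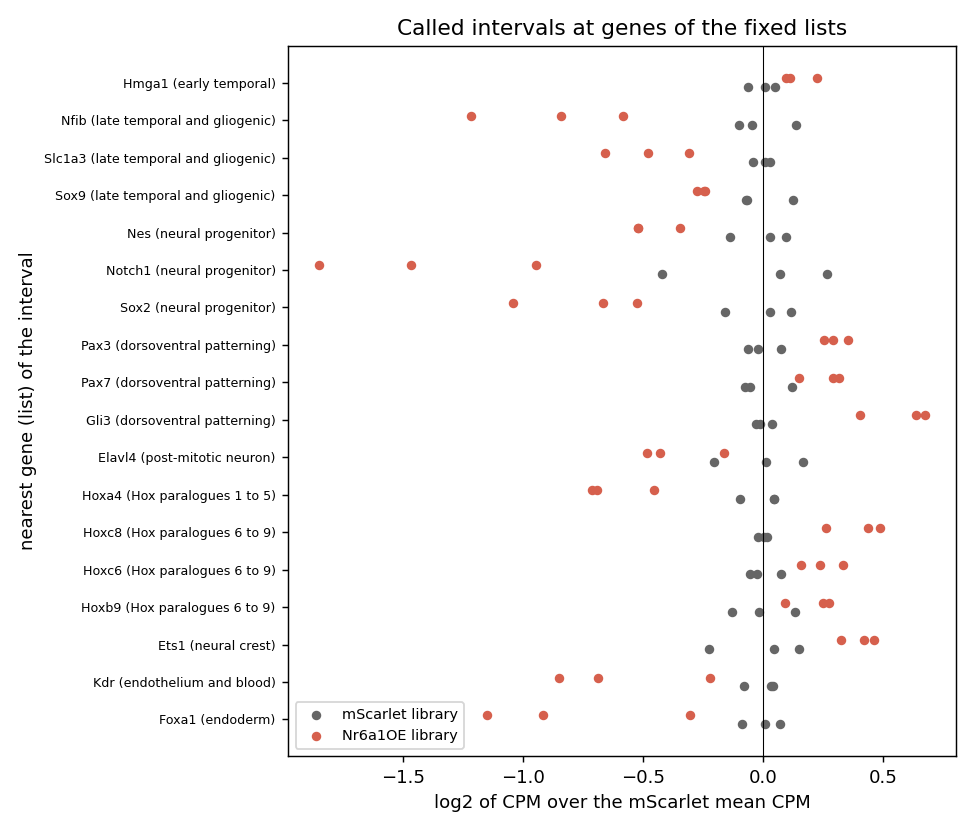
Each line is 1 called interval reported in the text, named by its nearest gene and list, and each point is 1 library, placed by the log2 of its CPM over the mScarlet mean CPM, with 3 mScarlet and 3 Nr6a1OE libraries per interval. The Nr6a1OE libraries of Nes and Hoxa4 lie below all mScarlet libraries, and those of Pax3 and Gli3 lie above them.

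Whole chromosomes also differed. Chromosome 11 held 9.06 ± 0.0210% of fragments in mScarlet and 9.39 ± 0.0266% in Nr6a1OE, and chromosome 6 held 6.09 ± 0.0103% and 5.93 ± 0.0356% (SD, n = 3 each). The median log2 fold change was 0.06 on chromosome 11 (95% bootstrap interval 0.0528 to 0.0640) and -0.03 on chromosome 6 (-0.0379 to -0.0250), against -0.0140 to 0.0126 on the other 18 chromosomes. All 13 stretches of 10 Mb on chromosome 11 had a median above 0, and all 15 on chromosome 6 one below 0. The shares of the 3 Nr6a1OE libraries did not overlap those of the 3 mScarlet libraries on either chromosome, and for 3 against 3 libraries 0.1 is the smallest p that an exact permutation test can give. Chromosome 11 held 45 opened and 28 closed intervals, and chromosome 6 held 2 opened, near Hnrnpa2b1 and Ret (named after their values were seen), and 62 closed. With chromosome medians removed, 810 of the 894 called intervals were among 856 calls, and chromosome 11 had 14 opened and 44 closed, a change of more than 1.5 times in both, and chromosome 6 had 9 opened and 47 closed.

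**Figure D3:**
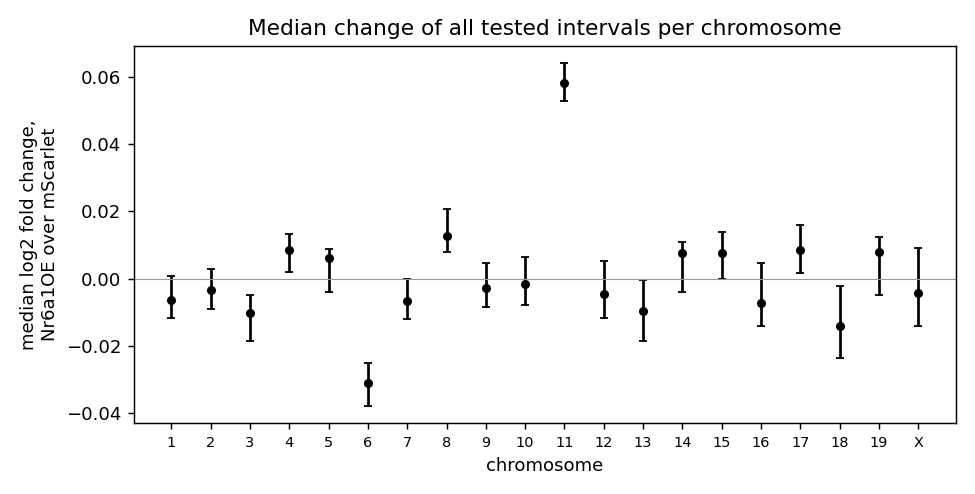
Points are the median log2 fold change of Nr6a1OE over mScarlet over all tested intervals of each chromosome, with chromosome on the horizontal axis, and bars are 95% bootstrap intervals over intervals, from 2000 draws. Chromosome 11 stands at 0.06 and chromosome 6 at -0.03, apart from the range of -0.0140 to 0.0126 of the others.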

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

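The summed pair of libraries, the assumed variation, the removal of chromosome medians, the omission of chromosomes 6 and 11 and the assignment to gene bodies were chosen after seeing the data. No result changed direction past its threshold. More intervals closed than opened under every setting, and closed intervals stayed depleted within 1 kb of a gene end, with 2.78 to 8.09% on leaving out 1 library and 0 to 9.53% over the other settings that kept the 1 kb limit. DESeq2 gave 4 opened and 99 closed intervals, all among the 894 edgeR calls, with 2158 at an unadjusted p under 0.05, 0% of opened near a gene end (Fisher's exact test, p = 0.578) and 0.30 at the Nr6a1 interval (adjusted p = 0.0875). Its 4 opened intervals lay nearest to Meis1, Enc1, Gsdmc and Cdon, named after their values were seen. DESeq2 used a median trended dispersion of 0.0219, against 0.000684 in edgeR, and put 77.4% of intervals at its smallest single-interval estimate. Its median final dispersion was 0.0193, so its test took a wider spread than those single-interval estimates gave. With an assumed variation of 10% between cultures, 19 opened and 205 closed intervals were called and the Nr6a1 interval (0.30) was not (adjusted p = 0.563), nor were Nes (0.09996), Pax3 (0.587), Gli3 (0.1475), Pax7 (0.778) or the Hox6 to Hox9 intervals (0.468 to 0.951). At 20% edgeR called 0 opened (446 at an unadjusted p under 0.05) and 29 closed, with 0.30 at the Nr6a1 interval not called and Hoxa4 lost (adjusted p = 1), because the larger assumed spread widens every error. An adjusted p under 0.01 gave 80 opened and 342 closed, a log2 fold change of at least 1 gave 22 and 154 and set aside the Nr6a1 interval (0.30), and a mean of at least 50 fragments gave 430 closed, since fewer intervals were tested. The share of opened intervals near a gene end was 28.9% at 3 kb (p = 0.334) and 20.5% with loess offsets (p = 0.140, Fisher's exact tests). The camera adjusted p with an estimated correlation was 0.245 for early temporal, 0.342 for Hox6 to Hox9 and 0.245 for cell cycle, and with a 20 kb limit 0.171 for early temporal and 0.143 for cell cycle. Apart from the assumed spread and the smaller number of intervals, the cause was not tested. Leaving out each library gave 98 to 190 opened and 395 to 544 closed intervals, 12.3 to 20.5% of opened near a gene end, and adjusted p of 0.04997 to 0.101 for early temporal, 0.0120 to 0.138 for cell cycle and 2.15e-05 to 0.0334 for Hox6 to Hox9, which kept its call. Hoxc6 and Hoxb9 lost their calls with limma voom (adjusted p = 0.0512 for both), and Hoxb9 and Hmga1 with upper-quartile scaling (0.05003 and 0.0541). The share closed among calls was 69.7 to 75.7% over 5 scalings. With the replicate number as a block, 224 opened and 617 closed, all 841 shared with the fit without it, and of 81 called intervals at the genes described 1 was lost, at Irx3 (0.31, adjusted p = 0.0577). Deviations of samples with the same number correlated at 0.0044, -0.0022 and -0.0063, and 1 of 6 samples correlated best with its own number, so no pairing by number was seen. Since the spread between libraries was close to counting noise, these correlations cannot exclude pairing. With Nr6a1OE 1 and 3 summed, 224 opened and 638 closed. Under the small simulated spread, changes of 0.3 on the log2 scale were recovered in 30% of planted intervals at this depth. The GC-content offsets, alone and with the replicate block, and the 3 motif alternatives were not run.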

Other observations

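The tests at Cdh11 and of strong intervals, gene density, scaling and abundance were chosen only after the result was seen, and the tests of copy number, of other splits and of axon guidance genes were written before. Cdh11, which encodes a mesenchymal cadherin, lost accessibility at 4 of the 9 intervals inside it or within 100 kb (log2 fold change -1.42 to -0.62), with p = 3.02e-06 in an exact hypergeometric test, which did not pass when adjusted by Benjamini-Hochberg over both directions and 15864 genes (adjusted p = 0.0957, or 0.0479 over closed intervals alone). That test takes intervals as independent, which neighbouring ones may not be. Several closed intervals also lay at Nrxn3, a synaptic adhesion gene (4 of 35), the neuronal transcription factor gene Mef2c (3 of 12), the ephrin receptor gene Epha3 (3 of 9) and the Slit receptor gene Robo2 (3 of 18), and none of these passed that test (adjusted p = 1). Of the intervals nearest to Mef2c, 2 more closed, at -1.28 and -1.08, but lay more than 100 kb from it and so outside that count. The most abundant interval of all, near Col19a1 on chromosome 1 (24612791 to 24613613), was called opened, from 373 ± 29.6 to 437 ± 24.0 CPM (SD, n = 3 each), a log2 fold change of 0.23 with an SE of 0.026 (edgeR adjusted p = 1.22e-14). Whether mitochondrial reads or reads of repeated sequence were placed in this interval was not checked. The treatment of such reads is not given, so the rise cannot be read as opened chromatin near Col19a1. The genes of this paragraph were singled out after their values were seen.

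The losses at Robo2, Epha3 and Unc5c prompted the hypothesis that intervals at axon guidance receptors and ligands closed more often than others. Over all such families 13 of 508 intervals closed (odds ratio 2.08, 2-sided Fisher's exact test, p = 0.0151). Without those 3 genes 5 of 473 closed, at Dcc, Robo1, Sema3e and Sema6a, with an odds ratio of 0.844 (95% interval 0.272 to 1.99, Fisher's exact test, p = 1), so no excess was seen beyond the genes that prompted it, and an excess of up to the upper bound stays open.

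Chromosome 11 was higher and chromosome 6 lower in all 3 Nr6a1OE libraries. A few strong intervals do not account for this, since the uncalled intervals had a median log2 fold change of 0.0577 on chromosome 11 and -0.0278 on chromosome 6. Chromosome 7, the most gene-dense autosome, had 14.0 genes per Mb, against 13.2 on chromosome 11, and a median of -0.00679. Gene density alone therefore does not account for the rise of chromosome 11. That comparison rests on 1 chromosome and does not cover chromosome 6 or GC content. A copy-number difference of chromosome 11 in part of the cells is a candidate explanation. It would take about 8.13% more cells with an extra copy if that were the whole cause. The medians near gene ends (0.0434) and elsewhere (0.0705) both lay above 0 and differed by -0.0271, within the limits written beforehand for a copy-number difference. Their bootstrap intervals did not meet, a condition that those limits did not include. On chromosome 6 the medians were -0.0292 near gene ends and -0.0319 elsewhere, with intervals that overlapped. Copy number still cannot be told apart from regulation here, since these counts hold no separate measure of it. An effect of Nr6a1 itself on these chromosomes also stays open, and was not tested.

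More intervals closed than opened. All 5 scalings used counts in the intervals, so a scaling to background reads was not covered. The choice among these 5 does not account for the excess of closed intervals, since the lowest number of closed intervals per opened interval was 2.30. Nor does a trend of the change with abundance, which would have to lower other intervals as abundant as the closed ones, since all tested intervals at that abundance had a median log2 fold change of 0.0105 (95% bootstrap interval 0.0077 to 0.0133). A lower signal over background, GC content, a shift in the mix of sorted cells and repression by Nr6a1 stay open and were not tested.

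The real grouping called 894 intervals and the highest of the other splits called 0 by edgeR, with 1835 to 2554 intervals at an unadjusted p under 0.05 against 6508 for the real one. The 6 libraries make 10 splits into 3 and 3, of which 1 called as many intervals as the real grouping, namely itself, and 10 are too few for a share under 0.05.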
